A study of Homo sapiens with 12 samples.

How the data were processed

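RNA was measured in 12 spleen samples of human T-ALL cells grown in mice, 3 mice for each of 2 xenografts given DMSO and 3 for each given decitabine. Per the labels' protocols, mice were randomised, RNA was extracted with a miRNeasy kit, and libraries were made with the Lexogen QuantSeq 3′ FWD kit. That kit tags the end of each transcript, so counts were not scaled by gene length. The deposited values are raw counts of reads per gene for each library. The submitters' processing notes name STAR 2.4.2a, DESeq2 and the builds GRCh38 and hg38, and the role of each is not given in the sources used here. The deposited count table holds 29250 gene rows and 4 rows of reads not assigned to a gene, which are unmapped, multimapping, outside genes or ambiguous. The names of these rows match STAR's gene counts. The annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. A second deposited table, named as normalised, held the same values as the raw table and was not used here. Alignments to the mouse genome were not analysed here.

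Of the gene rows, 28801 matched the gene symbols and GRCh38 positions of GENCODE release 29. In all, 55 sex-linked genes were left out because the cells came from patients, and 3382 genes had no reads. The libraries held 2097852 to 15089475 reads in genes. Unassigned reads were 17.4% unmapped, 12.9% multimapping, 11.1% outside genes and 5.20% ambiguous in T-ALL1 DMSO, and 29.6%, 12.0%, 9.41% and 4.38% in T-ALL1 decitabine. They were 12.1%, 15.5%, 8.97% and 5.54% in T-ALL2 DMSO, and 20.2%, 13.5%, 11.1% and 4.85% in T-ALL2 decitabine. The top 10 genes held 7.24%, 7.34%, 11.0% and 9.29% of reads in the same groups. No library of a group was a copy of another, since the reads of each pair differed by more than counting error (chi-square per degree of freedom of 1.89 to 6.86). Changes from the group mean in libraries with the same replicate number were uncorrelated (-0.09 to 0.092), so libraries were not paired.

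The 5 comparisons were T-ALL1 decitabine against DMSO, T-ALL2 decitabine against DMSO, both together with equal weight, the interaction (the change in T-ALL2 minus that in T-ALL1), and T-ALL2 against T-ALL1 under DMSO. Genes with enough reads were kept with edgeR's filterByExpr (minimum of 10 reads), which left 11278. Counts were scaled by TMM and fitted in 1 model of all 12 libraries with edgeR 4.0.16's robust quasi-likelihood test in R 4.3.3. A gene was called at an adjusted p (Benjamini-Hochberg) under 0.05. The biological coefficient of variation was 0.1085. CPM values use TMM-scaled library sizes, and all adjusted p of single genes come from this edgeR test unless another tool is named. Where a group had no reads of a gene, the fold is a bound against 3 counts over the group. Where it had between 1 and 5 counts, the ratio of pooled reads is given with its 95% exact counting interval. Fitted folds of such genes depend on the prior count. Values of 1 quantity were compared by exact permutation of libraries within xenografts.

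The 35 gene lists, the comparisons, the alternatives and the named-gene rule were fixed before the data were examined. The rule named the 10 called genes with the largest rise and the 10 with the largest fall per comparison, among genes with at least 5 CPM in the higher group whose groups did not overlap. For the interaction, overlap of groups was not considered. The rule also named, per list, up to 4 members with the smallest p over both xenografts and up to 4 in each, called or not. DNMT1, DNMT3A, DNMT3B, UHRF1, DCK, CDKN1A and MYC were always named. The text gives a selection of these genes. PAGE5, CTAG2, MAGEB1 and genes given for a further comparison than the one that the rule named them in were chosen after their values were seen. The lists covered interferon-stimulated genes, nucleic acid sensors, cancer-testis antigens, germline genes under promoter methylation, p53 targets, S-phase genes, G2 and M phase genes, MYC-regulated ribosome biogenesis, NOTCH1 targets, early T-cell progenitor genes, cortical and mature T-cell genes and T-ALL transcription factor oncogenes. They also covered HLA class I and antigen processing, HLA class II, DNA methylation machinery, nucleoside uptake and metabolism, BCL2 family and caspases, imprinted genes, DNA damage repair, immediate early and heat shock genes, the integrated stress response, NF-kB targets, cytosolic ribosomal protein genes, numbered zinc fingers, clustered HOX and protocadherin genes and histones. Marker lists of erythroid, myeloid, B, NK and cytotoxic, megakaryocyte, endothelial and stromal cells were included. A list of mitochondrially encoded genes had 0 genes in the count table. The 27 lists with at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation and with fry. Lists too small for camera were summed per library and tested by exact permutation, a test added after the counts were seen.

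Alternatives were RLE and upper-quartile scaling, no low-count filter, DESeq2 1.42.0's Wald test, limma voom, a fit of only the groups compared, the replicate number as a block, each library left out in turn, and a minimum change of 2-fold. Alternatives chosen after seeing the data were library size only, a T-ALL2 share subtracted from T-ALL1 decitabine libraries, and T-ALL2 DMSO replicate 2 thinned to the depth of the next deepest. The T-ALL2 share was estimated from 18 marker genes with at least 50 CPM in T-ALL2 DMSO and at most 2% of that in T-ALL1 DMSO. The scripts were tested on simulated counts of 10933 tested genes with changes planted in 200 genes. With edgeR, 75.0% of genes planted at log2 1 and 89.9% of those at log2 2 were called in T-ALL1, 79.2% and 93.9% in T-ALL2, and 87.5% and 99.0% over both. Calls of genes without a planted change numbered 8, 11 and 9. Permutations and figures used python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.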

Results

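The libraries came from human T-cell acute lymphoblastic leukaemia (T-ALL), a cancer of immature T cells, grown in mice as patient-derived xenografts. 2 xenografts, T-ALL1 and T-ALL2, were each carried by mice given either DMSO, the solvent, or 0.5 mg/kg of decitabine for 5 days. Decitabine is a cytidine analogue that traps DNA methyltransferases after it is built into DNA, so that methylation is lost as cells divide. Tumour cells were taken from the spleen on day 7 and their messenger RNA was measured by 3′ tag sequencing. The 12 libraries formed 4 groups of 3 mice each. The libraries held between 2097852 and 15089475 reads in genes. T-ALL2 DMSO replicate 2 was the deepest, and the next deepest held 4018528. Levels are given as CPM, raw read counts divided by the TMM-scaled library size. Intervals and floors cover counting error only, and p-values measure the spread between mice that carry the same leukaemia, so the spread between patients was not measured. The first principal component, which held 75.8% of the variance, separated T-ALL1 from T-ALL2.

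Decitabine libraries held a larger share of reads that did not align to the human genome. In T-ALL1 this share was 17.4% ± 0.71 (SD, n = 3) under DMSO and 29.6% ± 3.4 (SD, n = 3) under decitabine. In T-ALL2 it was 12.1% ± 0.85 (SD, n = 3) and 20.2% ± 1.8 (SD, n = 3). The rise was 12.2 points in T-ALL1 (two-sided exact permutation p = 0.1, the smallest that 3 mice against 3 can give) and 8.04 points in T-ALL2 (exact permutation p = 0.1). With both xenografts permuted within themselves, the mean rise of 10.1 points gave an exact p of 0.005, the smallest that 400 arrangements allow. The share of reads in genes was 53.4% and 44.6% in T-ALL1, and 57.9% and 50.4% in T-ALL2, for DMSO and decitabine.

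**Figure D1:**
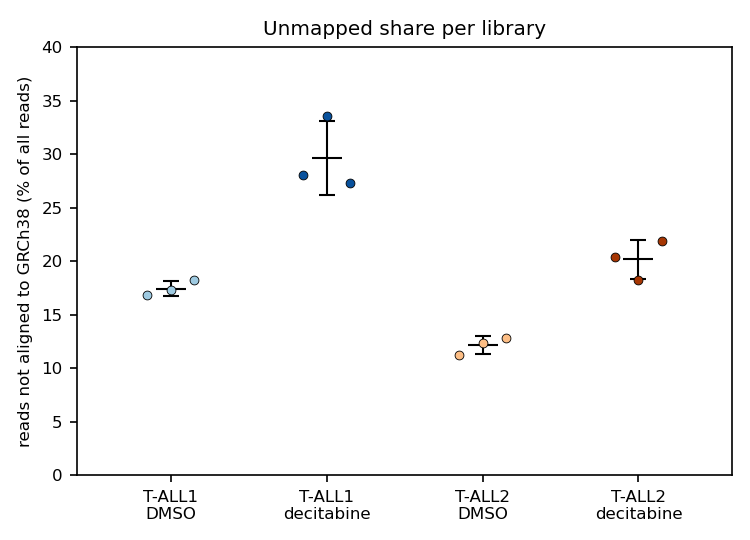
Share of all reads that did not align to the human genome (percent), per library, with the mean and SD of each group of 3 mice. All 3 decitabine libraries lay above all 3 DMSO libraries in each xenograft.

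The first comparison asked which genes decitabine changed in T-ALL1. PNMA5, from a family related to the paraneoplastic Ma antigens, had no reads under DMSO and 22.9 ± 10.3 CPM (SD, n = 3) under decitabine, at least 76.7-fold higher. CEBPE, a transcription factor of late granulocyte development, rose from 15.3 ± 3.89 to 196 ± 19.2 CPM. GZMA, a granule protease of cytotoxic lymphocytes, rose from 3.56 ± 0.671 to 103 ± 50.1 CPM. WT1, a zinc finger transcription factor expressed in many leukaemias, rose from 2.72 ± 0.935 to 24.8 ± 6.85 CPM. AHR, the aryl hydrocarbon receptor, fell from 81.2 ± 25.8 to 26.6 ± 5.6 CPM, and the growth regulator MYC fell from 53.7 ± 9.05 to 23.9 ± 5.31 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 changes were 3.66 for CEBPE (SE 0.17, adjusted p = 3.14e-17), 4.84 for GZMA (SE 0.57, 0.000507) and 3.15 for WT1 (SE 0.29, 3.51e-09). They were -1.62 for AHR (SE 0.21, 1.92e-06) and -1.17 for MYC (SE 0.24, 0.00252). For PNMA5 the adjusted p was 1.84e-08. In each of these genes, all 3 decitabine libraries lay on the same side of all 3 DMSO libraries. The named-gene rule required this of the largest changes, so it adds no support. PNMA5 lies on chromosome X (GRCh38, 152988824 to 152994127).

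In T-ALL1, 869 of 11278 genes were higher and 433 were lower under decitabine, and 508 and 49 of these changed at least 2-fold. The groups did not overlap in 2904 genes (25.7%), where chance gives 10%, and 1211 of the 1302 called genes were among them. Without T-ALL1 DMSO replicate 2 the count of lower genes was 211, and without T-ALL1 DMSO replicate 1 it was 239.

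Some genes of myeloid and cytotoxic cells rose in T-ALL1 from very low levels. In the list of NK and cytotoxic markers, 8 of 12 members rose and none fell, both over all genes and adjusted over the list alone (camera adjusted p = 3.09e-05, and 0.248 with an estimated correlation). FCER1G, an adaptor of Fc and NK receptors, went from 0.114 to 4.45 CPM, a ratio of 44.6 (95% counting interval 7.43 to 1820). In the myeloid list, 3 of 6 members rose and none fell (adjusted p = 0.00241, estimated correlation 0.248). S100A8, a calcium-binding protein of neutrophils and monocytes, had no reads under DMSO and 10.6 ± 8.21 CPM under decitabine, at least 35.0-fold higher. Its partner S100A9 rose from 1.14 ± 0.887 to 16.3 ± 7.78 CPM. TRIB1, a pseudokinase that regulates myeloid differentiation, rose to 22.2 CPM (log2 3.16). RNASE3, an eosinophil granule ribonuclease, went from 0.0953 to 46.9 ± 36.2 CPM, a ratio of 467 (83.3 to 18500). RNASE3 was called at an adjusted p of 0.00278 with all libraries and not without T-ALL1 DMSO replicate 1 (0.0523, range over alternatives 6.2e-15 to 0.0523). Since mouse reads were not separated from human reads, these myeloid and cytotoxic reads were not shown to be human.

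Some transcription factors and markers of immature lymphoid cells also rose in T-ALL1. Of the early T-cell progenitor genes, 4 of 12 rose and 1 fell, again with the same counts over the list alone (adjusted p = 0.0409, estimated correlation 0.248). Of the T-ALL transcription factor oncogenes, 4 of 13 rose and none fell, and 5 rose when adjusted over the list alone (adjusted p = 0.00752, estimated correlation 0.248). ZEB2, a repressor of epithelial genes that acts in immature T cells, rose from 5.69 to 19.8 CPM (log2 1.79, adjusted p = 0.00021). MYCN, a relative of MYC, rose from 3.48 to 11.5 CPM (log2 1.71), while MYC itself fell. LYL1 rose by 1.31 and GATA2, a factor of blood stem cells, by 1.54 on the log2 scale. VPREB1 and IGLL1, which form the surrogate light chain of B-cell precursors, rose from 5.97 to 29.6 CPM and from 3.02 to 20.7 CPM. Among T-cell genes, CD8A rose from 58.7 to 123 CPM. LEF1, a partner of beta-catenin, fell by 0.42 on the log2 scale.

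Some antigen presentation, p53 target and erythroid genes rose in T-ALL1. Of HLA class I and antigen processing genes, 7 of 20 rose and none fell, and 9 rose and 1 fell over the list alone (adjusted p = 0.0059, estimated correlation 0.303). CALR, a chaperone of class I assembly, rose from 48.1 to 98.1 CPM (log2 1.03, adjusted p = 1.08e-05), and CANX rose from 522 to 781 CPM (log2 0.58). Of p53 targets, 8 of 41 rose and 1 fell, and 9 rose and 3 fell over the list alone (adjusted p = 0.0409, estimated correlation 0.248). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 6.83 to 16.8 CPM (log2 1.28, SE 0.24, adjusted p = 0.000328). The pro-death genes BBC3 and BMF rose by 1.23 and 1.70 on the log2 scale. Of erythroid markers, 2 of 5 rose, and 4 rose and 1 fell over the list alone (adjusted p = 0.0152, estimated correlation 0.303). ALAS2, the first enzyme of haem synthesis in red cells, rose from 2.33 to 9.67 CPM (log2 2.05, adjusted p = 0.00138), while HBB, adult beta globin, was not called (231 ± 149 and 1010 ± 443 CPM, adjusted p = 0.0697). Mouse reads were not separated from human reads, so the erythroid reads were not shown to be human.

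A few genes of cell division and ribosome production fell in T-ALL1. Of G2 and M phase genes, 7 of 53 fell and none rose, with the same counts over the list alone (adjusted p = 0.000284, estimated correlation 0.303), and 3 fell with upper-quartile scaling. CENPA, the centromeric histone, fell by 0.56 on the log2 scale. Of S-phase genes, 5 of 43 fell and none rose, also over the list alone (adjusted p = 0.00659, estimated correlation 0.518). Of MYC-regulated ribosome biogenesis genes, 8 of 43 fell and none rose, and 11 fell and 2 rose over the list alone (adjusted p = 0.000484, estimated correlation 0.303). DDX21, a nucleolar helicase, fell from 423 to 279 CPM (log2 -0.60, adjusted p = 0.00459). LTB, lymphotoxin beta, fell from 2922 ± 718 to 1430 ± 159 CPM (SD, n = 3), the NOTCH target HES1 from 39.2 to 21.7 CPM and the retinaldehyde dehydrogenase ALDH1A2 from 228 ± 42.4 to 78.7 ± 28.9 CPM. ETV3, a transcriptional repressor, fell from 14.6 to 5.07 CPM (log2 -1.52).

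In T-ALL1, 10 lists passed camera with its preset correlation and 0 passed with an estimated correlation, where 5 of the 27 lists had an unadjusted p under 0.05. With the preset correlation the p53 and early progenitor lists were past the threshold narrowly. The p53 list ended above it in 8 alternatives (up to 0.0916), among them without T-ALL1 DMSO replicate 2 or 3, T-ALL2 DMSO replicate 3 or any T-ALL1 decitabine library. The S-phase list did so without T-ALL1 DMSO replicate 1 or T-ALL1 decitabine replicate 3 (up to 0.128), and the early progenitor list without T-ALL1 DMSO replicate 3 or T-ALL1 decitabine replicate 1 (up to 0.0916).

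The second comparison asked the same of T-ALL2, where most NK and cytotoxic markers rose and most ribosomal protein genes fell. GNLY, the pore-forming granulysin, rose from 4.53 ± 0.839 to 108 ± 29.7 CPM (SD, n = 3). TBX21, the T-bet factor of cytotoxic programmes, went from 0.228 to 13.4 ± 3.33 CPM, a ratio of 91.8 (95% counting interval 30.6 to 452). KLF2, a factor of T-cell quiescence and exit from the thymus, rose from 108 ± 9.76 to 307 ± 41.4 CPM, and its target S1PR1 from 36.5 ± 3.43 to 113 ± 11.9 CPM. DNTT, the terminal transferase of immature lymphocytes, fell from 565 ± 39.1 to 197 ± 18.1 CPM. In log2 terms GNLY rose by 4.67 (SE 0.23, adjusted p = 1.5e-16), KLF2 by 1.51 (SE 0.13, 2.84e-10) and S1PR1 by 1.62 (SE 0.14, 2.84e-10), and DNTT fell by 1.52 (SE 0.21, 0.000699). The adjusted p for TBX21 was 3.53e-09. All 3 decitabine libraries lay on the same side of all 3 DMSO libraries in each of these genes, again as the rule required of the largest changes.

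In T-ALL2, 859 of 11278 genes were higher and 739 were lower under decitabine, 310 and 83 of them at least 2-fold. Higher genes made up 53.8% of the calls with TMM scaling and 79.8% with library size only, which moved the median log2 change of all genes by 0.124. The groups did not overlap in 4015 genes (35.6%), against 10% by chance, and 1543 of the 1598 called genes were among them. Without T-ALL2 decitabine replicate 3 the counts were 462 higher and 359 lower. The count of higher genes was 571 without T-ALL2 decitabine replicate 1. The count of lower genes was 428 without that library, 471 without T-ALL2 DMSO replicate 1 and 468 without T-ALL2 DMSO replicate 3.

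Of NK and cytotoxic markers in T-ALL2, 8 of 12 rose and none fell, also over the list alone (adjusted p = 2.84e-21, estimated correlation 0.0599). KLRD1, the CD94 chain of NK receptors, rose from 0.318 to 8.76 ± 4.15 CPM (SD, n = 3). KLRB1 rose from 45.7 to 157 CPM and the pore-forming PRF1 from 21.2 to 53.6 CPM. The fractalkine receptor CX3CR1 rose from 3.77 to 39.0 ± 6.21 CPM and GIMAP4, a GTPase of lymphocyte survival, from 5.21 to 61.4 ± 18.8 CPM. The steroid-reducing enzyme AKR1C2 rose from 0.221 to 10.6 ± 1.54 CPM, a ratio of 72.4 (24 to 358). KIR3DL2, a receptor for HLA class I on NK cells, rose from 0.382 to 5.61 CPM (log2 3.92, adjusted p = 3.92e-06).

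Some progenitor, interferon and sensor genes rose in T-ALL2. Of early T-cell progenitor genes, 5 of 12 rose and 1 fell, and 6 rose and 1 fell over the list alone (adjusted p = 0.00246, estimated correlation 0.0883). LMO2 and TAL1, partner factors of T-ALL, rose from 3.98 to 11.8 CPM (log2 1.68) and from 2.08 to 6.13 CPM (log2 1.54). Of interferon-stimulated genes, 8 of 44 rose and 1 fell, also over the list alone (adjusted p = 0.00227, estimated correlation 0.129), and 15 rose and none fell with library size only (median 0.396, against 0.27 with TMM). IFITM3, which blocks virus entry, rose from 60.4 to 115 CPM (log2 0.94, adjusted p = 1.1e-05). Of nucleic acid sensors and their signalling genes, 5 of 20 rose and none fell, also over the list alone (adjusted p = 0.00363, estimated correlation 0.154). SAMHD1, a dNTP hydrolase, rose from 3.09 to 15.4 CPM (log2 2.46), IRF1 from 219 to 353 CPM (log2 0.69) and TMEM173, which codes for STING, from 85.5 to 132 CPM (log2 0.63). Of erythroid markers, 3 of 5 rose, and 4 over the list alone (adjusted p = 0.00246, estimated correlation 0.238). ALAS2 rose from 0.771 to 7.84 CPM (log2 3.43), with mouse RNA again not excluded as a source. CDKN1A rose from 47.3 to 78.0 CPM (log2 0.73, adjusted p = 0.000906). UHRF2, which binds methylated and hydroxymethylated DNA, rose from 27.8 to 50.7 CPM (log2 0.87). The apoptosis inhibitor BIRC3, an NF-kB target, rose from 53.5 to 107 CPM (log2 0.99).

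Most ribosomal protein genes fell in T-ALL2. Of cytosolic ribosomal protein genes, 71 of 95 fell and 4 rose, and 77 fell and 5 rose over the list alone (adjusted p = 1.97e-27, estimated correlation 0.154). This was so for 69 of the 79 protein-coding members, with a median log2 change of -0.439, while among the 16 pseudogenes and other members 4 rose and 2 fell. With library size only the list's median was -0.29 and 53 members fell, and no scaling turned its direction. RPL5 fell from 3032 ± 169 to 1901 ± 51.9 CPM (SD, n = 3) and RPS29 from 22790 to 13720 CPM. Pseudogenes such as RPL12P2, which rose by 1.18, share sequence with their parent genes, so their counts are uncertain. Of MYC-regulated ribosome biogenesis genes, 11 of 43 fell and 1 rose, and 11 fell and 2 rose over the list alone (adjusted p = 0.00107, estimated correlation 0.344). With library size only, 5 fell and 2 rose, and the median was -0.07 instead of -0.196. FBL, the methyltransferase of ribosomal RNA, fell from 1363 to 889 CPM. Of cortical and mature T-cell genes, 8 of 44 rose and 11 fell, and the list did not pass (adjusted p = 0.376). CD1A fell from 200.2 to 77.7 CPM, IL7R from 154 to 83.6 CPM and PTCRA, the pre-T-cell receptor chain, from 3.38 to 0.117 CPM, a ratio of 24.9 (95% counting interval 4.32 to 1000). NOTCH3 fell from 13.3 to 4.59 CPM. Of B cell markers, 3 of 7 fell and 1 rose, also over the list alone (adjusted p = 0.00312, estimated correlation 0.13), although the list's mean was only -0.03. JCHAIN, which joins immunoglobulin chains, fell from 133 to 51.2 CPM. The largest falls also included RNU6ATAC, a minor spliceosomal RNA (log2 -2.13), and CPLX1, a regulator of vesicle fusion, which fell from 32.7 to 7.87 CPM (log2 -2.03).

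Of the 8 lists past camera in T-ALL2, 0 passed with an estimated correlation, where 6 of 27 had an unadjusted p under 0.05. The erythroid list ended at 0.0753 and the B cell list at 0.409 with no low-count filter.

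The third comparison asked what both xenografts shared. PTGER2, a prostaglandin receptor, and SP140, a nuclear body protein of immune cells, rose in both. CEBPE was called over both, but T-ALL2 alone did not pass (adjusted p = 0.0551). There CEBPE had 1 read under DMSO and 5 under decitabine, a ratio of 12.6 (95% counting interval 1.41 to 597). It was near silent in T-ALL2, so a rise shared by both was not shown. PTGER2 rose from 0.209 to 6.14 CPM in T-ALL1, a ratio of 30.9 (95% counting interval 8.05 to 263), and from 1.53 to 5.90 CPM in T-ALL2. SP140 rose from 0.0953 to 3.89 CPM, a ratio of 38.8 (6.4 to 1590), and from 1.46 to 6.37 CPM. AKR1C2 rose from under 1 CPM in both, to 3.70 CPM in T-ALL1, a ratio of 12.5 (3.82 to 64.3), and 10.6 CPM in T-ALL2. DUSP6, a phosphatase that restrains ERK signalling, fell by 0.90 on the log2 scale over both (adjusted p = 0.000184) and NINJ2, a surface adhesion protein, by 0.91 (2.55e-08). The fall of DUSP6 was larger in T-ALL1 than in T-ALL2 (interaction adjusted p = 0.0192). NINJ2 fell from 217 to 156 CPM in T-ALL1 and from 90.4 to 35.4 CPM in T-ALL2. Adjusted p over both xenografts was 1.61e-07 for PTGER2, 2.28e-06 for SP140, 3.22e-09 for AKR1C2 and 2e-04 for CEBPE. In these genes the groups did not overlap in either xenograft. The named-gene rule required this of the largest changes, so it adds no support.

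Over both xenografts, 1021 genes were higher and 629 were lower, 410 and 22 of them at least 2-fold. Higher genes made up 61.9% of calls, and 77.8% with library size only. Of the genes called higher in T-ALL1 and in T-ALL2, 255 were the same, where 66.2 would be shared if calls were independent (Fisher's exact p = 1.98e-91). Of those called lower, 58 were the same, against 28.4 if independent (Fisher's exact p = 1.52e-07). Both tests treat genes as independent, which they are not, so these p-values do not measure the spread between mice. Of the 364 genes called in both, 313 changed in the same direction. Leaving out T-ALL2 decitabine replicate 3 lowered that count to 178. Across all tested genes, which are not independent replicates, the changes in both xenografts were only weakly related (r = 0.21, rho = 0.11).

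**Figure D2:**
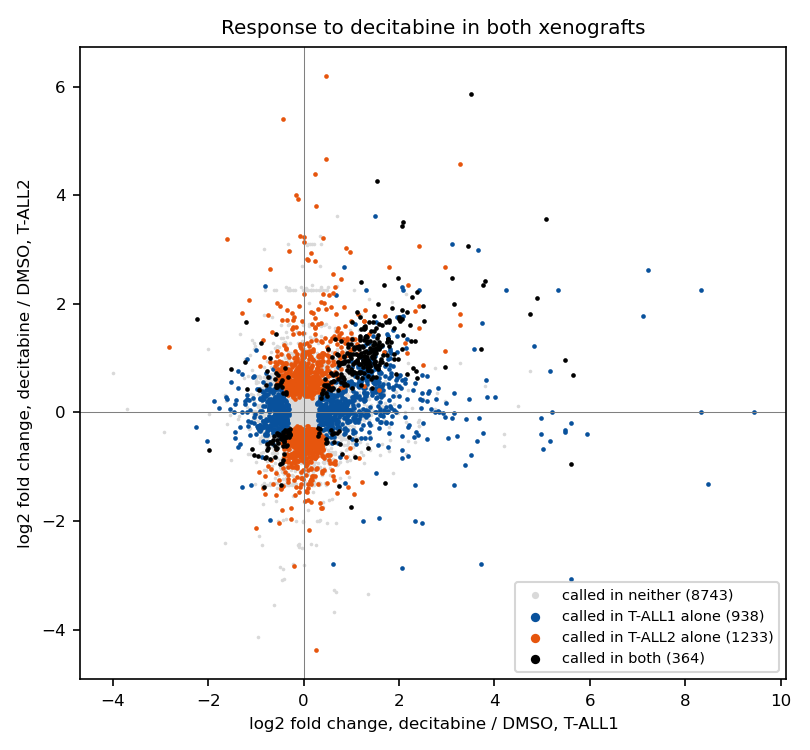
Log2 change under decitabine in T-ALL1 (horizontal) and T-ALL2 (vertical), with each point a gene. The 364 genes called in both lie mainly in the upper right and lower left, and the folds of genes with few reads depend on the prior count.

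Among lists, 10 of 12 NK and cytotoxic markers rose over both xenografts (11 over the list alone, adjusted p = 1.17e-07, estimated correlation 0.136), as did 4 of 5 erythroid markers (4 up and 1 down over the list alone, 8.98e-05, estimated correlation 0.136). PRF1 rose by 1.26 and KLRB1 by 1.62 on the log2 scale. HBB was higher by 2.16 (adjusted p = 0.0144) and ALAS2 by 2.74, but host mouse RNA was not excluded as the source of erythroid reads. Of early progenitor genes, 5 of 12 rose and 1 fell (6 and 1 over the list alone, adjusted p = 0.000482, estimated correlation 0.0829), and 6 of 13 T-ALL transcription factor oncogenes rose (7 up and 1 down over the list alone, 0.0019, estimated correlation 0.0829). LYL1 rose by 1.11. Of HLA class I genes, 7 of 20 rose (9 over the list alone, adjusted p = 0.00121, estimated correlation 0.236), with HLA-B higher by 0.48, and of p53 targets 10 of 41 rose and 1 fell (10 and 2 over the list alone, 0.0135, estimated correlation 0.136). CDKN1A rose by 1.00 and BBC3 by 0.93, while PMAIP1, another pro-death p53 target, fell by 0.47. Of ribosomal protein genes, 42 of 95 fell and 9 rose (56 and 9 over the list alone, adjusted p = 7.26e-08, estimated correlation 0.499), through T-ALL2, where 71 fell, against 3 in T-ALL1. Of ribosome biogenesis genes, 14 of 43 fell and 2 rose (23 and 2 over the list alone, adjusted p = 1.16e-06, estimated correlation 0.209). NPM1, a nucleolar chaperone, fell by 0.36. Of NOTCH1 targets, 6 of 16 fell (7 down and 1 up over the list alone, adjusted p = 0.00661, estimated correlation 0.198).

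NK and cytotoxic, erythroid, early progenitor and ribosome biogenesis lists also passed in each xenograft alone, and NOTCH1 targets in neither. Of the 9 lists, 0 passed with an estimated correlation, where 6 of 27 had an unadjusted p under 0.05.

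**Figure D3:**
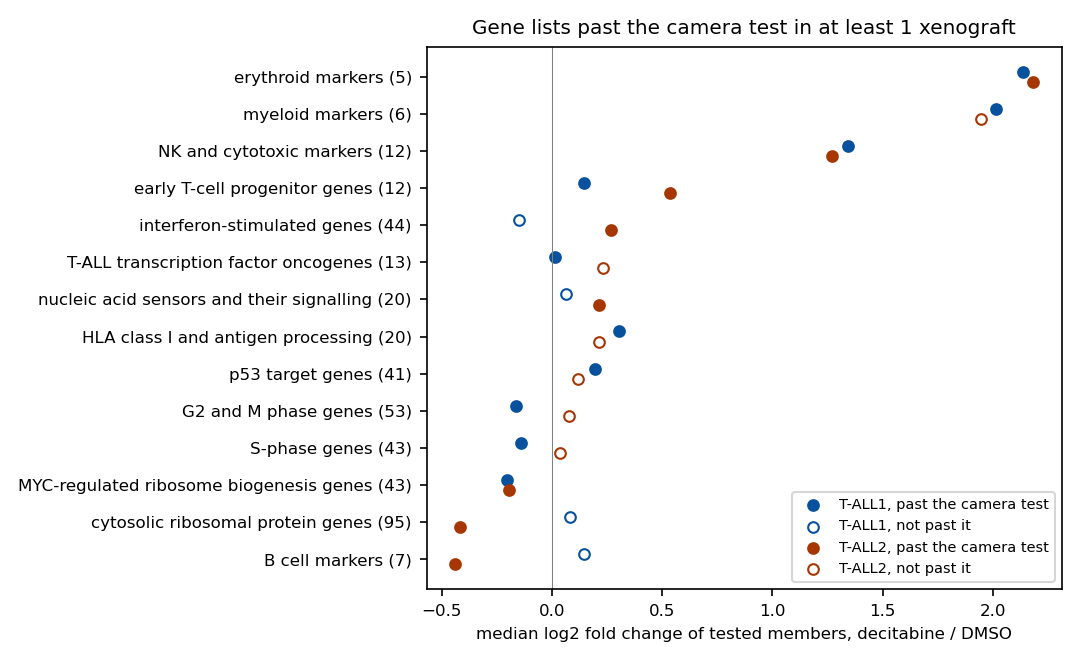
Median log2 change under decitabine of the tested members of 14 gene lists in T-ALL1 and T-ALL2, with filled points where the list passed camera. Putting members with no reads in a group at their bound shifted medians by up to 1.05, for myeloid markers in T-ALL2.

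Few transcripts of enzymes that decitabine acts on or needs were called as changed. Protein was not measured, and a gene that was not called may still have changed. Neither DNMT3A nor DNMT3B, the de novo methyltransferases, nor UHRF1, the cofactor of maintenance methylation, nor DCK, the kinase that activates decitabine, was called in T-ALL1, in T-ALL2 or over both. Over both xenografts their adjusted p was 0.21, 0.431, 0.722 and 0.605. In T-ALL1, DCK was at 0.172 and was called in 3 of 21 alternatives, among them without T-ALL1 decitabine replicate 1 (0.00401, range 0.00401 to 0.472). DNMT1, the maintenance methyltransferase, was not called in T-ALL1 (0.599). It rose from 321 to 388 CPM in T-ALL2 (log2 0.28, SE 0.09, adjusted p = 0.0404), a call that ended in 9 of 21 alternatives (range 0.0022 to 0.153), among them without any 1 of the 6 T-ALL2 libraries or T-ALL1 DMSO replicate 1 (0.0535 to 0.152). Of the 22 genes of the DNA methylation machinery list, 1 rose over both and none fell (adjusted p = 0.704, median 0.01 although the test pointed down). Of 23 nucleoside uptake and metabolism genes, 4 rose and 1 fell over both, with an adjusted p of 0.67.

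Cancer-testis antigens, a class of germline proteins shut by promoter methylation in most body cells, had too few reads to be tested singly. Their summed level rose from 0.834 ± 1.16 to 12.5 ± 4.54 CPM (SD, n = 3) in T-ALL1 and from 0.263 ± 0.287 to 2.08 ± 0.489 CPM (SD, n = 3) in T-ALL2. The exact permutation p over both xenografts was 0.005, the smallest 400 arrangements allow, and 0.0233 after adjustment over 7 small lists whose sums were tested after the counts were seen. Members with a read went from 6 to 14 of 20 in T-ALL1 and from 4 to 6 in T-ALL2. PAGE5 had 3 reads under DMSO and 33 under decitabine in T-ALL1. CTAG2 went from 0 to 15 reads in T-ALL1 and from 0 to 8 in T-ALL2, and MAGEB1 from 0 to 14 and from 0 to 4. The summed HLA class II and clustered protocadherin lists each passed (exact p = 0.01, adjusted 0.0233), but not without their most-read member (exact p = 0.325 and 0.1). In the HLA class II list that member was a cathepsin, so no rise of HLA genes was shown. Clustered HOX genes (exact p = 0.2), megakaryocyte and platelet markers (0.82), endothelial markers (0.16) and stromal markers (0.06) did not pass. Of 7 tested germline genes under promoter methylation, 1 rose and 1 fell over both (camera adjusted p = 0.67). RPL10L, a testis-expressed ribosomal protein gene, was higher over both by 1.88 (adjusted p = 0.00056), and the meiotic cohesin gene STAG3 was lower by 0.73 (0.000124). The call of RPL10L ended in 2 of 21 alternatives in T-ALL1 alone (up to 0.058) and in 4 of 20 in T-ALL2 alone (up to 0.105).

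The other lists did not pass in T-ALL1, in T-ALL2 or over both. Over both xenografts, 11 of 44 cortical and mature T-cell genes rose and 10 fell (adjusted p = 0.704). Of 26 BCL2 family and caspase genes, 6 rose and 4 fell (0.67), with BCL2L1, a survival factor, lower by 0.43. Of 54 DNA damage repair genes, 4 rose and 5 fell (0.262). Of 31 immediate early and heat shock genes, 5 rose and 3 fell (0.756), with HSPB1 lower by 0.68. Of 27 integrated stress response genes, 3 rose and 2 fell (0.741). Of 19 NF-kB targets, 3 rose and 1 fell (0.64), and of 14 imprinted genes 1 rose and none fell (0.64). Of 332 numbered zinc finger genes, 6 rose and 3 fell (0.359), and of 35 histone genes 1 rose and 2 fell (0.348). The direction of the test differed from the median or mean in a few of these lists over both xenografts, such as immediate early genes and nucleoside metabolism.

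The fourth comparison asked where the response to decitabine differed between the xenografts, as tested by the interaction of xenograft and treatment. WT1 and IGLL1 rose in T-ALL1 and were not called in T-ALL2 (interaction adjusted p = 7.02e-07 and 3.35e-06). KIR3DL2 was 189 and 176 CPM in T-ALL1 and rose in T-ALL2 (2.33e-05). LPCAT4, an enzyme of phospholipid remodelling, fell from 27.6 to 5.73 CPM in T-ALL1 and rose from 2.25 to 9.25 CPM in T-ALL2, and its interaction log2 change was 3.95 (0.00149). The call of its rise in T-ALL2 ended in 5 of 21 alternatives (range 9.98e-06 to 0.0892, highest without T-ALL2 decitabine replicate 2). BMF rose from 4.17 to 13.3 CPM in T-ALL1 and fell from 12.4 to 4.94 CPM in T-ALL2 (2.33e-05). RUBCNL, a regulator of autophagy, rose from 68.7 to 137 CPM in T-ALL1 and fell from 7.24 to 2.11 CPM in T-ALL2 (8.38e-05). S1PR1 (6.08e-05), LTB (0.000305) and JCHAIN (0.000705) also differed.

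The interaction was called for 455 genes with a higher and 548 with a lower change in T-ALL2 than in T-ALL1. Genes with the higher change made up 45.4% of the calls, 33.9% with upper-quartile scaling and 70.5% with library size only, which moved the median of all genes by 0.133. With 1 library left out these counts ran from 231 (without T-ALL2 decitabine replicate 3) to 623 (without T-ALL2 DMSO replicate 2) and from 326 (without T-ALL2 DMSO replicate 3) to 778 (without T-ALL1 decitabine replicate 1).

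Of 95 ribosomal protein genes, 57 had a lower change in T-ALL2 and none a higher change, and 71 over the list alone (adjusted p = 3.28e-26). In T-ALL1, 14 members rose and 3 fell, and the list did not pass (0.0633). Of these, 6 of the 79 protein-coding members rose and none fell, while 8 of the 16 pseudogenes and other members rose and 3 fell. Interferon-stimulated genes had a higher change in T-ALL2 for 10 of 44 members and a lower one for 2 (16 and 4 over the list alone, adjusted p = 0.000329). In T-ALL1, 5 of them rose and 8 fell (0.0939). EPSTI1 and CMPK2 fell there from 111 to 71.1 CPM and from 79.6 to 47.9 CPM, while MX2, a restriction factor, rose from 27.3 to 55.3 CPM. The change in T-ALL2 was higher for 6 of 53 G2 and M phase genes and lower for none (11 over the list alone, adjusted p = 4.15e-05). It was higher for 3 of 43 S-phase genes, also over the list alone (0.00284). Of B cell markers, 4 of 7 had a lower and 1 a higher change (5 and 2 over the list alone, 0.0213). With an estimated correlation 0 of these 5 lists passed, where 3 of 27 had an unadjusted p under 0.05. The adjusted p was then 0.327 for ribosomal protein genes and B cell markers, 0.171 for interferon-stimulated genes, 0.371 for G2 and M phase and 0.654 for S phase. The B cell list ended above the threshold without T-ALL1 decitabine replicate 2 and with no low-count filter (up to 0.383).

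The genes with the largest interaction were mostly near silent in 1 xenograft. PDE4A, a cAMP phosphodiesterase, had no reads in T-ALL1 under DMSO, reached 1.97 CPM under decitabine, at least 6.71-fold higher, and went from 57.1 to 43.3 CPM in T-ALL2 (interaction adjusted p = 0.0119). It was 1 of 18 T-ALL2 marker genes with reads in T-ALL1 decitabine libraries, and its excess there was 3.94%, 0% and 7.81% of its T-ALL2 level, so its rise was not shown to be expression by T-ALL1 cells. ZSCAN9 (0.0105) and the non-coding LINC01451 (0.00951) had the same pattern, at least 4.79-fold and 3.83-fold higher in T-ALL1. The rise in T-ALL1 was not called for PDE4A without T-ALL1 decitabine replicate 3 (0.0599, range 4.9e-05 to 0.0599), nor for LINC01451 without T-ALL1 decitabine replicate 2 (0.0502, range 0.0029 to 0.0502). RAB44, a large GTPase of granulocytes and mast cells, rose from 0.209 to 7.40 CPM in T-ALL1, a ratio of 37.4 (95% counting interval 9.84 to 317), and was 1.38 and 0.855 CPM in T-ALL2 (0.000263). LTBP4, a matrix protein that binds TGF-beta, was 6.13 and 4.54 CPM in T-ALL1 and went from no reads to 1.37 CPM in T-ALL2, at least 9.26-fold higher (0.00208). Of the 20 genes with the largest interaction, 9 lost their call in between 3 and 13 alternatives each and 4 in 1 alternative. MYC was not called (interaction log2 0.92, adjusted p = 0.0649) and was called in 6 of 21 alternatives (range 0.000642 to 0.201), among them without T-ALL1 decitabine replicate 1 (0.036) or T-ALL2 DMSO replicate 2 (0.000642). GNLY (0.0641) and DNTT (0.0656) were not called either, so their changes in T-ALL2 were not shown to differ from those in T-ALL1.

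**Figure D4:**
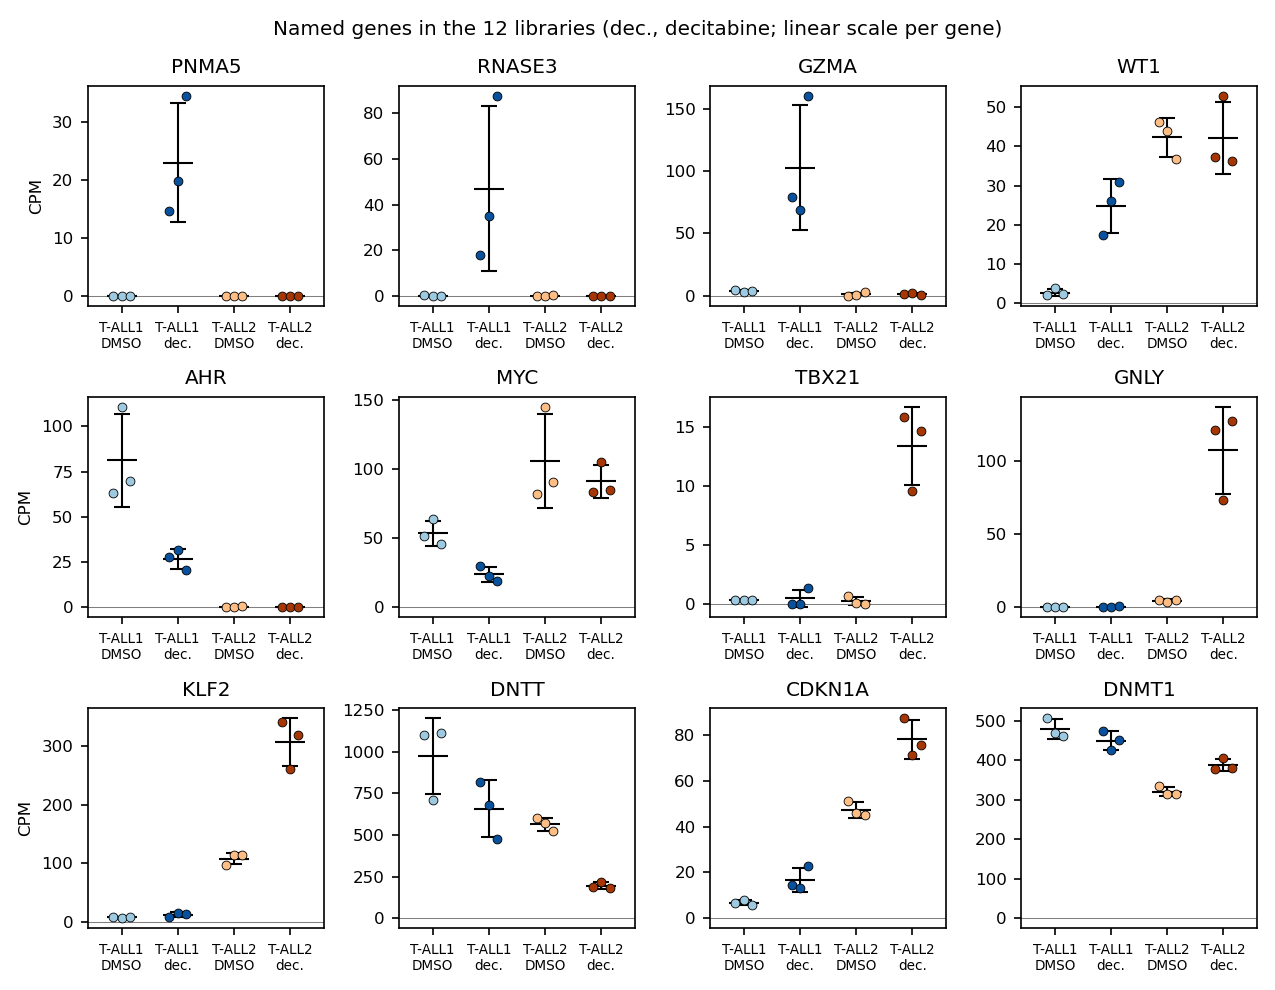
CPM of 12 genes in each library, with the mean and SD of each group of 3 mice, on linear axes that include 0. GZMA, WT1 and RNASE3 were higher with decitabine in T-ALL1, and GNLY, TBX21 and KLF2 in T-ALL2.

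The fifth comparison described how the xenografts differed under DMSO. TLX3, a homeobox factor, was 527 ± 69 CPM (SD, n = 3) in T-ALL2 and 1.18 CPM in T-ALL1 (log2 8.76, adjusted p = 4.22e-09). MSRB3, a methionine sulfoxide reductase, had no reads in T-ALL1 and 72.2 CPM in T-ALL2, at least 244-fold higher, and CGAS, the cytosolic DNA sensor, at least 91.4-fold higher. TMEM98, a membrane protein, had 121 CPM in T-ALL1 and no reads in T-ALL2, at least 820-fold lower, and RTL8A, a retrotransposon-derived gene, was at least 451-fold lower. ALDH1A2 was 228 CPM in T-ALL1 and 0.121 CPM in T-ALL2, a ratio of 925 (95% counting interval 396 to 2850). The RNA-binding protein gene KHDRBS3 was 151 and 0.299 CPM, a ratio of 1030 (351 to 4990). Among genes chosen after their values were seen, TAL1 was 74.6 ± 5.33 CPM in T-ALL1 and 2.08 ± 0.222 CPM in T-ALL2 (log2 -5.13, adjusted p = 8.56e-20). KLF2 was 7.19 and 108 CPM (log2 3.92, 7.2e-19), and IL7R 9.24 and 154 CPM (log2 4.05, 2.64e-20).

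Under DMSO, 3057 genes were higher and 3133 were lower in T-ALL2 than in T-ALL1, 1317 and 1443 of them at least 2-fold. Higher genes made up 49.4% of calls, and 28.9% with library size only, which moved the median by -0.275. The groups did not overlap in 6899 genes (61.2%), against 10% by chance. CDKN1A was higher in T-ALL2 by 2.77 on the log2 scale and MYC by 1.00. UHRF1, DNMT1 and DNMT3A were lower in T-ALL2, with log2 differences of -1.12 (adjusted p = 1.33e-05), -0.58 (1.95e-06) and -0.44 (0.00108). DCK (0.213) and DNMT3B (0.19) were not called, and with library size only both were called lower in T-ALL2, as was DCK without T-ALL2 DMSO replicate 2 (0.036). The ranges of adjusted p over the alternatives were 0.0257 to 0.559 for DCK and 0.0122 to 0.641 for DNMT3B. Each xenograft stands for 1 leukaemia, so these differences describe 2 leukaemias and not kinds of T-ALL. Gene lists were not tested here.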

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

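The tests of cell types and of mouse RNA in this part were chosen after the results were seen, and the counts of other splits were planned. Groups of 3 were too small to test for single outlying libraries. What follows are results whose change under decitabine differed between T-ALL1 and T-ALL2, by the interaction of xenograft and treatment, and a signal in reads outside genes.

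The interaction was called by edgeR's quasi-likelihood test for 455 genes with a higher and 548 with a lower change in T-ALL2. Splits were drawn at random, with or without DMSO and decitabine exchanged in T-ALL2, and in 100 of them 1 (the real split) called as many genes. The highest of the others called 223. Among all 200 arrangements 2 called as many, the other being the real split with that exchange (1650), and the highest of the rest called 375. Splits other than these 2 mix treated with untreated mice, which also removes any effect of decitabine that both xenografts share. So the splits test whether treatment mattered at all, and cannot tell whether the responses differed. For lists chance cannot be excluded, since 54 of 100 splits gave as many lists as the real 5, up to 12. The lists were cytosolic ribosomal protein genes (camera adjusted p = 3.28e-26), G2 and M phase genes (4.15e-05), interferon-stimulated genes (0.000329), S-phase genes (0.00284) and B cell markers (0.0213). With an estimated correlation 0 of these passed (0.327, 0.371, 0.171, 0.654 and 0.327).

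Of 98 genes named in the comparisons, 37 had an interaction adjusted p under 0.05. Genes that rose in T-ALL1 with a higher change there were WT1 (7.02e-07), IGLL1 (3.35e-06), BMF (2.33e-05), RUBCNL (8.38e-05), RAB44 (0.000263), VPREB1 (0.000807), MX2 (0.000814), CANX (0.00176), LINC01451 (0.00951), ZSCAN9 (0.0105), PDE4A (0.0119), MSRB3 (0.00814), CALR (0.0139) and PTGER2 (0.0315). Genes that fell in T-ALL1 and had a higher change in T-ALL2 were LTB (0.000305), ETV3 (0.000519), LPCAT4 (0.00149), CMPK2 (0.00242), EPSTI1 (0.00329), HES1 (0.00472), CENPA (0.0113) and DUSP6 (0.0192). Genes that rose in T-ALL2 with a higher change there were KIR3DL2 (2.33e-05), S1PR1 (6.08e-05), LMO2 (0.000696), TAL1 (0.00176), LTBP4 (0.00208), BIRC3 (0.00214), UHRF2 (0.00868), IRF1 (0.00923) and TBX21 (0.0309). Genes with a lower change in T-ALL2, where they fell, were RPS29 (0.000312), JCHAIN (0.000705), IL7R (0.000879), RPL5 (0.00116), NINJ2 (0.00459) and PTCRA (0.00837).

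Some of these interactions rested on single libraries. CALR and IRF1 were not called without T-ALL1 DMSO replicate 2 (0.0506 and 0.0509), CENPA without T-ALL2 decitabine replicate 2 (0.0525) and MSRB3 without T-ALL1 decitabine replicate 3 (0.149). The rise of MSRB3 in T-ALL1, also 1 of the 18 T-ALL2 marker genes found there, was not called without that library either (0.189, range 0.00119 to 0.189). DUSP6 was not called without T-ALL1 decitabine replicate 3 (0.0892), T-ALL2 DMSO replicate 1 (0.0509) or T-ALL2 decitabine replicate 2 (0.0531). TBX21 lost its call in 8 alternatives, without any T-ALL1 DMSO library, T-ALL1 decitabine replicate 2, T-ALL2 DMSO replicate 2 or 3, or T-ALL2 decitabine replicate 1 or 3. Its highest adjusted p was 0.0861, without T-ALL1 DMSO replicate 1. PTGER2 lost its call in 10, with the replicate block and without T-ALL1 DMSO replicate 1 or 2, T-ALL1 decitabine replicate 2 or 3, T-ALL2 DMSO replicate 1 or 2, or any T-ALL2 decitabine library. Its highest was 0.125, without T-ALL1 DMSO replicate 2. The ranges of adjusted p were 0.00361 to 0.0506 for CALR, 0.00197 to 0.0509 for IRF1, 0.00266 to 0.0525 for CENPA, 0.000557 to 0.149 for MSRB3, 1e-07 to 0.0892 for DUSP6, 0.00134 to 0.0861 for TBX21 and 0.025 to 0.125 for PTGER2.

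NK and cytotoxic list genes rose in both xenografts, 8 of 12 in each, and 3 of 6 myeloid list genes rose in T-ALL1. With an estimated correlation none of these lists passed (0.248 in T-ALL1 for both lists, 0.0599 for the first in T-ALL2). The highest differed, although the interaction was called for neither GZMA (0.272) nor GNLY (0.0641). GZMA reached 103 CPM in T-ALL1 decitabine and 1.23 CPM in T-ALL2 decitabine, and GNLY 0.422 and 108 CPM. A single kind of NK or cytotoxic cell in both spleens, as the only source of the rise, would raise the markers in like proportions. Yet without GZMA and GNLY the make-up of the rise overlapped by at most 43.3% between xenografts, and by at least 70.5% within 1. Human myeloid cells that express LYZ, MPO, CD14, CSF1R, CSF3R and S100A12 would raise these genes. Yet the summed change of these genes was -0.239% of the rise of S100A8 and S100A9. This argues against such myeloid cells, and the overlap argues against a single kind of cytotoxic cell as the only source in both spleens. Several of these markers are also expressed by T-ALL cells. So a shared cytotoxic cell beside a change in the leukaemia cells was not excluded. Myeloid cells without these genes, and different cytotoxic cells in each spleen, were not tested. T-ALL2 RNA in T-ALL1 libraries cannot be told apart from expression for part of these genes, since 9 of the 11 stayed called after a T-ALL2 share was subtracted. Host mouse RNA or expression by the leukaemia cells themselves may explain the rest, and neither was tested for these genes.

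Reads that did not align to the human genome made up 29.6% in T-ALL1 decitabine and 20.2% in T-ALL2 decitabine, above DMSO in both, and HBB rose over both. Human red cell precursors would bring HBA1, HBA2, AHSP, SLC4A1 and CA1, and these summed to 0.187% of HBB reads in the decitabine libraries. AHSP, SLC4A1 and CA1 together went from 0.317 to 1.71 CPM in T-ALL1 and from 0.313 to 0.613 CPM in T-ALL2. Multimapping reads were not assigned to genes, which can lower HBA1 and HBA2, so human red cell precursors were not excluded. Host mouse RNA could raise both the unmapped share and HBB, and within groups the share rose with HBB (Pearson r = 0.614, exact permutation p = 0.0293, rho = 0.664, p = 0.0301, 12 libraries, the only relation computed). Without the 2 farthest libraries r was 0.731. Whether mouse reads also aligned to other human genes was not tested gene by gene, and a change in the make-up of the spleen under decitabine stays open as untested.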

How the results depend on the processing

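The alternatives with library size only, a subtracted T-ALL2 share and a thinned library were chosen after seeing the data, and the others and the counts of splits were planned.

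Of 463 single results, each a gene in a comparison, 322 kept their direction and their side of the threshold in every alternative run, and 0 reversed. Calls made with all libraries and again in an alternative never had opposite signs. DESeq2 shared 1098 of the 1302 calls in T-ALL1 and 1328 of 1598 in T-ALL2, and limma voom 1119 and 1491. RLE scaling shared 1262 and 1592. Upper-quartile scaling, RLE scaling, no filter, DESeq2 and limma voom left each count of called genes within 1.5 times its value.

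A minimum change of 2-fold, which removes calls by construction, left 508 higher and 49 lower genes in T-ALL1, 310 and 83 in T-ALL2, 410 and 22 over both, 196 and 204 for the interaction, and 1317 and 1443 between xenografts. Library size only gave 1489 higher and 377 lower genes in T-ALL2, 372 lower over both, 790 and 331 for the interaction, and 1954 and 4805 between xenografts. That scaling shifted the median log2 change of all genes by 0.124 in T-ALL2, 0.133 for the interaction and -0.275 between xenografts, and beyond that the cause was not tested. Fitting only the groups compared gave 237 lower genes in T-ALL1, and the cause was not tested. With an estimated correlation camera passed 0 lists in T-ALL1, 0 in T-ALL2, 0 over both and 0 for the interaction, with 5, 6, 6 and 3 lists at an unadjusted p under 0.05. Fry, which does not compare a list with other genes, passed 16 lists in T-ALL2 and 9 for the interaction.

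Leaving out single libraries gave 617 to 967 higher and 211 to 551 lower genes in T-ALL1, 462 to 975 and 359 to 859 in T-ALL2, and 790 to 1023 and 433 to 691 over both. It gave 231 to 623 and 326 to 778 for the interaction, and 2733 to 3164 and 2915 to 3344 between xenografts. Genes called in the same direction in both xenografts ran from 178, without T-ALL2 decitabine replicate 3, to 323. Fewer libraries lower the power, and why single libraries counted for more was not tested. Lists ran from 8 to 11 in T-ALL1 and in T-ALL2, 9 to 10 over both and 4 to 7 for the interaction.

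With the replicate number as a block, 842 higher and 435 lower genes were called in T-ALL1 and 868 and 748 in T-ALL2, but the numbers do not pair the mice, so the block tests nothing. With the T-ALL2 share subtracted T-ALL1 had 854 and 440 calls. With the deepest library thinned T-ALL2 had 829 and 710.

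For each single xenograft 10 splits are too few for a share under 0.05. In T-ALL1 the real split called 1302 genes with edgeR and 1 of 10 splits reached that, the highest other calling 0 (1072 at an unadjusted p under 0.05). It passed 10 lists against 6 (1 of 10). In T-ALL2 it called 1598 against 0 (1 of 10, highest other 509 unadjusted) and passed 8 lists against 8 (2 of 10). Between xenografts it called 6190 against 0 (1 of 10, highest other 389 unadjusted). Splits over both were drawn at random for each count separately, with or without DMSO and decitabine exchanged in T-ALL2. Over both, 1650 genes were called against at most 375 in the others drawn (1 of 100), so chance can be excluded for this count. The real split with that exchange was not in this draw and called 1003. In the other draw 313 genes were shared in direction against at most 51 (1 of 100), from the exchanged real split. All remaining splits shared 0, since they called 0 genes in at least 1 xenograft, so they do not test the sharing. Chance cannot be excluded for the 9 lists over both, as 10 of 100 splits gave as many, up to 12.

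Depth limits genes that were near silent in 1 group, where 1 to 3 reads set the lower level. The ratio of RNASE3 in T-ALL1 had an interval from 83.3 to 18500.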

Other observations

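The tests in this part were chosen after the results were seen.

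T-ALL1 decitabine replicate 3 held reads of genes that mark T-ALL2. Of 18 genes with high levels in T-ALL2 and almost none in T-ALL1 under DMSO, 17 lay above every T-ALL1 DMSO library in replicate 3, 12 in replicate 1 and 8 in replicate 2. The median excess of these markers was 2.84% of their T-ALL2 level in replicate 3, 0.705% in replicate 1 and 0.325% in replicate 2. T-ALL2 RNA or reads in that library may be a source, which cannot be told apart from expression by T-ALL1 cells, since 1 marker stayed within the DMSO range and decitabine could also switch on such genes. Whether it is the whole cause cannot be told apart either, as 1 marker needed at least a 7.57% share where another allowed at most 4.87%. After the median share of each library was subtracted, 97.2% of the genes called higher in T-ALL1 stayed called. A share of that size cannot account for most of these calls, and a larger share was not tested.

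Summed levels of marker lists gave the scale of these signals. NK and cytotoxic markers summed to 31.2 CPM under DMSO and 192 CPM under decitabine in T-ALL1, and 192 and 551 CPM in T-ALL2. Erythroid markers summed to 471 and 1511 CPM in T-ALL1 and 221 and 814 CPM in T-ALL2. The myeloid sum changed less, with 387 and 411 CPM in T-ALL1 and 200 and 163 CPM in T-ALL2. Yet the median log2 change of the 6 tested myeloid markers in T-ALL1 was 2.01, with 3 called higher and 0 lower, so the sum does not show the typical member. Summed stromal markers were 271 and 270 CPM in T-ALL1 and 56.5 and 83.8 CPM in T-ALL2. Several of these markers are also expressed by T-ALL cells, so the sums are not cell numbers.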
